A study of Chlorocebus sabaeus with 6 samples.

How the data were processed

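RNA was measured in 6 samples of COS7, a fibroblast-like line derived from the kidney of the African green monkey (Chlorocebus sabaeus) and immortalised with SV40. The groups, taken from the sample titles, were 3 wild-type samples (WT) and 3 samples with a knockout of both ATL2 and ATL3 (DKO). Per the labels' protocols, cells were lysed in TRIzol, total RNA was precipitated with isopropanol, and libraries were made with BGI's Optimal Dual-mode mRNA kit. The labels do not say whether the samples of a group came from separate cultures or how many knockout clones they represent, so p-values measure only the spread between these samples, which may be technical.

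The authors deposited one table of 18050 genes. Per the file headers it holds estimated counts per gene and sample, and the values show that 5.8 to 6.5% of the estimated counts per sample were not whole numbers, as happens when reads that match several genes are divided among them. Per the file headers it also holds FPKM values, which are counts scaled by the authors to the length of the transcript and to the depth of the library. HISAT and Bowtie2 are named in the submitters' processing notes. Their versions, the counting program and the genome build are not given in the sources used here. The table also has 9 columns of 3 other samples, which were not used. Gene names were those of the table. Of its gene IDs, 16730 (92.7%) matched the RefSeq annotation of assembly mChlSab1.0.hap1, which was used only to find which genes neighbour each other. Its coordinates are not reported, since the authors' build is not known. Fitted values of genes with near-identical copies, such as the ribosomal protein genes, are uncertain where reads were divided among copies.

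The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test after TMM normalization and the default filter on low counts by group (a minimum count of 10). The design fixed before the data were examined named this test for counts and a limma test on log2(FPKM + 1) for a table with FPKM only. The limma test was the one expected from the labels, and it was run as an alternative. Fold changes are DKO over WT, and adjusted p-values are from edgeR with Benjamini-Hochberg adjustment over the 13094 genes tested. Standard errors (SE) are the size of the log2 fold change divided by the root of the F statistic. An SE obtained this way is not a direct estimate of spread. Where a group has few counts, it can be smaller than counting error alone. A gene is called at an adjusted p below 0.05. Levels are means of the deposited FPKM values ± SD (n = 3 per group). Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library. With 1 to 3 counts over the group, the ratio is given with its exact 95% counting interval. Bounds and intervals cover counting error only.

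A set of 43 gene lists was fixed before the data were examined. Lists with at least 3 tested members (41) were tested with camera of limma 3.58.1 on log2 CPM (counts scaled to equal library totals), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Named genes followed a rule fixed at the same time: ATL1, ATL2 and ATL3; the 10 largest increases and 10 largest decreases among called genes with non-overlapping groups, at least 5 FPKM in the higher group and a gene symbol; and up to 4 members with the smallest adjusted p of each list with at least 3 called members or past camera. For other lists up to 2 members of the highest level could be named. A gene named outside this rule is said to be chosen after its values were seen.

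The alternatives were leaving out each sample in turn, the replicate number as a block, no filter on low counts, other normalizations, other tests (DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.01 and other filters), a stricter threshold, totals without the 100 most abundant genes, and for the lists an estimated correlation, fry, and the lists without shared genes. DESeq2 gives no matrix for camera and was not used for lists. Removing the trend with transcript length from the lists was added after seeing the data.

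The tests were checked on simulated counts drawn from the means and library sizes of these samples for DKO against WT, over 13094 genes. edgeR recovered 2% of 100 genes changed 1.5-fold, 52% of 50 changed 2-fold and 100% of 50 changed 4-fold, and 5.9% of its calls were false. DESeq2 recovered 19%, 72% and 100%, with 23.1% of calls false, and limma-voom 2%, 50% and 100%, with 4.8% false. Camera called the list simulated at 1.5-fold (adjusted p = 2.97e-25) and 0 of the 40 other lists. The simulated genes were drawn independently of each other, so this does not check camera on lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.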

Results

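Transcript levels of wild-type COS7 cells and of COS7 cells lacking ATL2 and ATL3 were compared in 3 samples each. ATL2 and ATL3 encode atlastins, membrane GTPases that fuse tubules of the endoplasmic reticulum (ER). The WT libraries held 15007799, 14923619 and 15127039 estimated counts and the DKO libraries 14289369, 14197344 and 15693049. Between 15272 and 15883 genes had counts in a library. The comparison asks how the transcriptome of COS7 cells differs when both atlastins are lost.

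The mRNAs of both targeted genes were lower in every DKO sample. ATL2 (gene ID 103220458) had 1276, 1211 and 1354 estimated counts in the WT samples and 320, 286 and 183 in the DKO samples. Its level was 30.6 ± 1.5 FPKM in WT and 5.94 ± 1.9 in DKO (SD, n = 3 each), a log2 fold change of -2.21 (SE 0.23, edgeR adjusted p = 0.00029). ATL3 (gene ID 103233661) had 1046, 956 and 989 counts in WT and 137, 156 and 107 in DKO, and 35.8 ± 1.36 against 4.88 ± 1.25 FPKM, a log2 fold change of -2.83 (SE 0.18, edgeR adjusted p = 3.7e-05). The DKO samples thus kept 21.2% of the WT level of ATL2, as a share of the library, and 13.8% of those of ATL3. In an exact two-sided permutation test each gene gave p = 0.1, the smallest that 3 samples against 3 allow. ATL1 (gene ID 103228960), the remaining atlastin, had 5 to 15 counts per library in all 6 samples and fell under the filter on low counts (exact two-sided permutation p = 0.3). Its summed counts, 36 in WT and 21 in DKO, put the DKO level at 59.5% of WT (exact 95% counting interval 33 to 105). These counts exclude neither a decrease within this interval nor an unchanged level. Without the filter its log2 fold change was -0.74 (SE 0.45, edgeR adjusted p = 0.25).

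**Figure D1:**
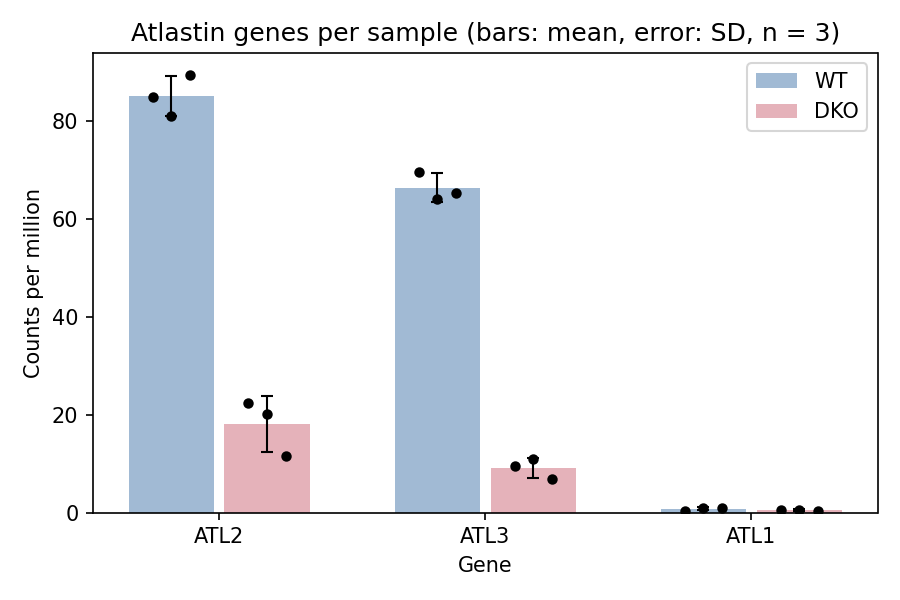
Counts per 1e6 counts of the library (CPM) of ATL2, ATL3 and ATL1 (vertical axis) in WT and DKO samples, with points for single samples, bars for the mean and error bars for the SD (n = 3). ATL2 averaged 85.2 in WT and 18.1 in DKO, ATL3 66.4 and 9.13, and ATL1 stayed near 0 in both.

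The genotypes differed widely. Of 13094 genes tested, 5959 (45.5%) were called by edgeR, 3055 higher and 2904 lower in DKO. With a log2 fold change of at least 1 in size, 2872 genes were called, 1287 higher and 1585 lower. The 3 samples of one genotype all lay above those of the other for 8192 genes, or 62.6% of those tested, where chance gives 10%. The first principal component held 88.2% of the variance and parted the genotypes. The second held 9.4% and set DKO replicate 3 apart from DKO replicates 1 and 2. At equal totals, DKO replicates 1 and 2 differed by a chi-square of 1.56 per gene and the WT pairs by 1.87 to 3.65, whereas DKO replicate 3 differed from the other DKO samples by 78.96 and 84.22. No pair agreed within sampling noise, and all 6 samples were counted separately. Repeat libraries of one culture can also exceed that noise, so this does not show that the samples were separate cultures. Without DKO replicate 3, 9880 of 13237 genes were called, 4770 higher and 5110 lower, among them 5932 of the 5959 in the same direction, and 2865 genes at the 2-fold limit.

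**Figure D2:**
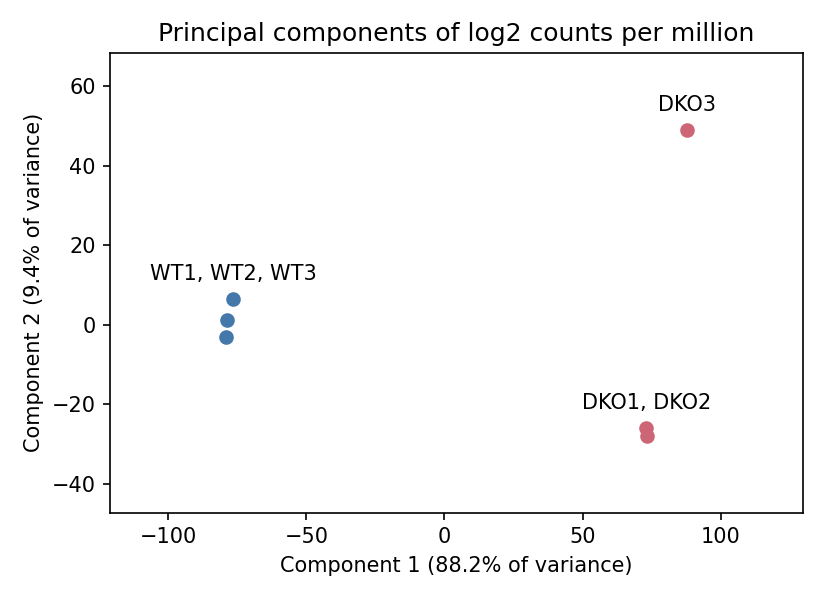
First and second principal components of log2 CPM, with one point per sample. The genotypes part along component 1 (88.2% of the variance), and DKO replicate 3 lies apart from DKO replicates 1 and 2 along component 2 (9.4%).

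The largest increases were in genes that WT cells hardly expressed. MYL9, a regulatory light chain of myosin, had 0 counts in every WT library and 87.4 ± 21.8 FPKM in DKO, at least 479-fold higher (edgeR adjusted p = 8.4e-05). TEK, the angiopoietin receptor TIE2, rose from 0.0467 ± 0.0153 to 15.1 ± 0.386 FPKM (log2 fold change 8.18, SE 0.22). The homeobox gene BARX1 rose from 0.913 ± 0.285 to 158 ± 5.93 FPKM (7.50, SE 0.24). The protease inhibitor gene CSTA reached 51.6 ± 22.6 FPKM from 0.203 ± 0.0924 (7.87, SE 0.52), and CCND2, which encodes cyclin D2, 14.1 ± 1.37 from 0.06 ± 0.0265 (7.82, SE 0.25). The caveolar gene CAVIN2 (7.55, SE 0.28), the transcription factor gene GATA4 (7.34, SE 0.46), the kallikrein gene KLK5 (6.95, SE 0.53), the progesterone receptor gene PGR (6.90, SE 0.48) and GLIPR1 (6.19, SE 0.22) completed the 10. The WT libraries together held 4 counts each of CSTA and KLK5, 5 of CAVIN2, 6 of GATA4 and 11 of TEK. They held 16 of GLIPR1 and 18 of CCND2. At counts this low the SE can be smaller than counting error alone. Without WT replicate 2, the log2 fold change was 9.09 for GATA4 and 8.21 for CAVIN2. The edgeR adjusted p-values of these 10 genes lay between 4.1e-06 and 8.4e-05.

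The largest fitted decreases were in genes at or near 0 counts in DKO. For a gene at 0 counts the fitted fold change follows its WT count, so the order does not rank the true decreases. COL11A1 and UCHL1, which are not among the 10, had ratios of 3330 and 2790, above the lower bounds given below. DSP, which encodes the desmosomal plaque protein desmoplakin, had 46.4 ± 1.29 FPKM in WT and 1 count in the 3 DKO libraries together, a ratio of 17700 with a 95% counting interval from 3180 to 701000. That count was in DKO replicate 3, and without this library DSP was at least 1910-fold lower. The other 9 genes had 0 counts in every DKO library. MGA, which encodes a MAX-binding transcription factor, was at least 404-fold lower, from 7.34 ± 0.334 FPKM. The kinase gene STK26 was at least 238-fold lower, EMB at least 217-fold and the matrix metalloproteinase gene MMP14 at least 204-fold. CPNE8 was at least 194-fold lower, BTBD3 at least 187-fold, the zinc finger gene ZNF518B at least 177-fold, DCDC2 at least 166-fold and ZNF528 at least 157-fold. The edgeR adjusted p-values of these 10 genes lay between 2.7e-06 and 2.1e-05.

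Of the 41 gene lists tested, 5 passed camera at an adjusted p below 0.05. Among all tested genes 45.5% were called, 3055 higher and 2904 lower, so called members alone do not mark a list, here or below. Of the lists past camera, heat shock and ribosomal proteins had a smaller share called than all genes. The cholesterol list had about the same share, and the ATF4 list and the ATF6 and XBP1 list a larger one. Of 31 tested targets of the unfolded protein response factors ATF6 and XBP1, 22 were higher, 0 lower and 9 not called (23 and 0 adjusted over the list alone, and 27 and 1 without DKO replicate 3), with a median log2 fold change of 0.61 (camera adjusted p = 0.00013). With an estimated correlation the camera adjusted p of this list was 0.25. The disulfide isomerase gene PDIA6 rose from 215 ± 3.25 to 546 ± 74.3 FPKM (1.38, SE 0.10), CRELD2 from 16.5 ± 0.618 to 58.3 ± 7.27 (1.88, SE 0.16), PDIA4 from 164 ± 2.61 to 295 ± 6.98 (0.89, SE 0.08) and HERPUD1, part of ER-associated degradation, from 23 ± 0.194 to 47.2 ± 1.23 (1.09, SE 0.10). Among 38 targets of ATF4 and the integrated stress response, 18 were higher, 3 lower and 17 not called (19 and 3 adjusted over the list alone, and 26 and 7 without DKO replicate 3), with a median of 0.38 (camera adjusted p = 0.014, and adjusted p = 0.66 with an estimated correlation). VLDLR, a lipoprotein receptor, rose from 0.94 ± 0.13 to 17.2 ± 0.596 FPKM (4.20, SE 0.15), the hormone gene STC2 from 0.847 ± 0.0907 to 7.74 ± 0.354 (3.23, SE 0.13) and the mitochondrial folate enzyme gene ALDH1L2 from 0.467 ± 0.0839 to 1.93 ± 0.332 (2.09, SE 0.19), while PSPH, the last enzyme of serine synthesis, fell from 24.4 ± 0.201 to 8.46 ± 0.718 (-1.48, SE 0.14).

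Of 24 tested targets of SREBP2, 11 were lower, 0 higher and 13 not called (14 and 0 adjusted over the list alone, and 19 and 0 without DKO replicate 3), with a median log2 fold change of -0.61 (camera adjusted p = 0.022, and adjusted p = 0.41 with an estimated correlation). The sterol reductase gene TM7SF2 fell from 6.73 ± 0.243 to 1.32 ± 0.254 FPKM (-2.29, SE 0.20), ACAT2 from 81.7 ± 2.09 to 37.1 ± 1.23 (-1.09, SE 0.10), HSD17B7 from 21.5 ± 0.488 to 10.6 ± 1.18 (-0.98, SE 0.12) and NSDHL from 62.5 ± 2.09 to 27.1 ± 3.25 (-1.16, SE 0.14). Of 22 cytosolic heat shock genes, 7 were higher, 0 lower and 15 not called (7 and 0 adjusted over the list alone, and 16 and 1 without DKO replicate 3; median 0.39, camera adjusted p = 0.022, and adjusted p = 0.41 with an estimated correlation). HSPA2 rose by a log2 fold change of 1.30 (SE 0.12), DNAJA1 by 0.70 (SE 0.11), DNAJB1 by 0.62 (SE 0.08) and the constitutive chaperone gene HSPA8 by 0.49 (SE 0.07). Of 70 cytosolic ribosomal protein genes, 24 were higher, 1 lower and 45 not called (20 and 1 adjusted over the list alone, and 35 and 20 without DKO replicate 3; median 0.23, camera adjusted p = 0.019, and adjusted p = 0.99 with an estimated correlation). RPS6 rose by 0.77 (SE 0.09), RPL6 by 0.73 (SE 0.09) and RPS12 by 0.96 (SE 0.16), while RPL39 fell to a log2 fold change of -0.92 (SE 0.10). The ribosomal list lay 0.47 higher (median log2) in DKO replicate 3 than in DKO replicates 1 and 2, and without that sample its median was 0.10 and its camera adjusted p 0.13. The other 4 lists stayed past 0.05 without DKO replicate 3. Fewer genes were called without WT replicate 1, 2 or 3: 7 lower in the cholesterol list in each case, and 12, 13 and 11 higher in the ribosomal list.

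**Figure D3:**
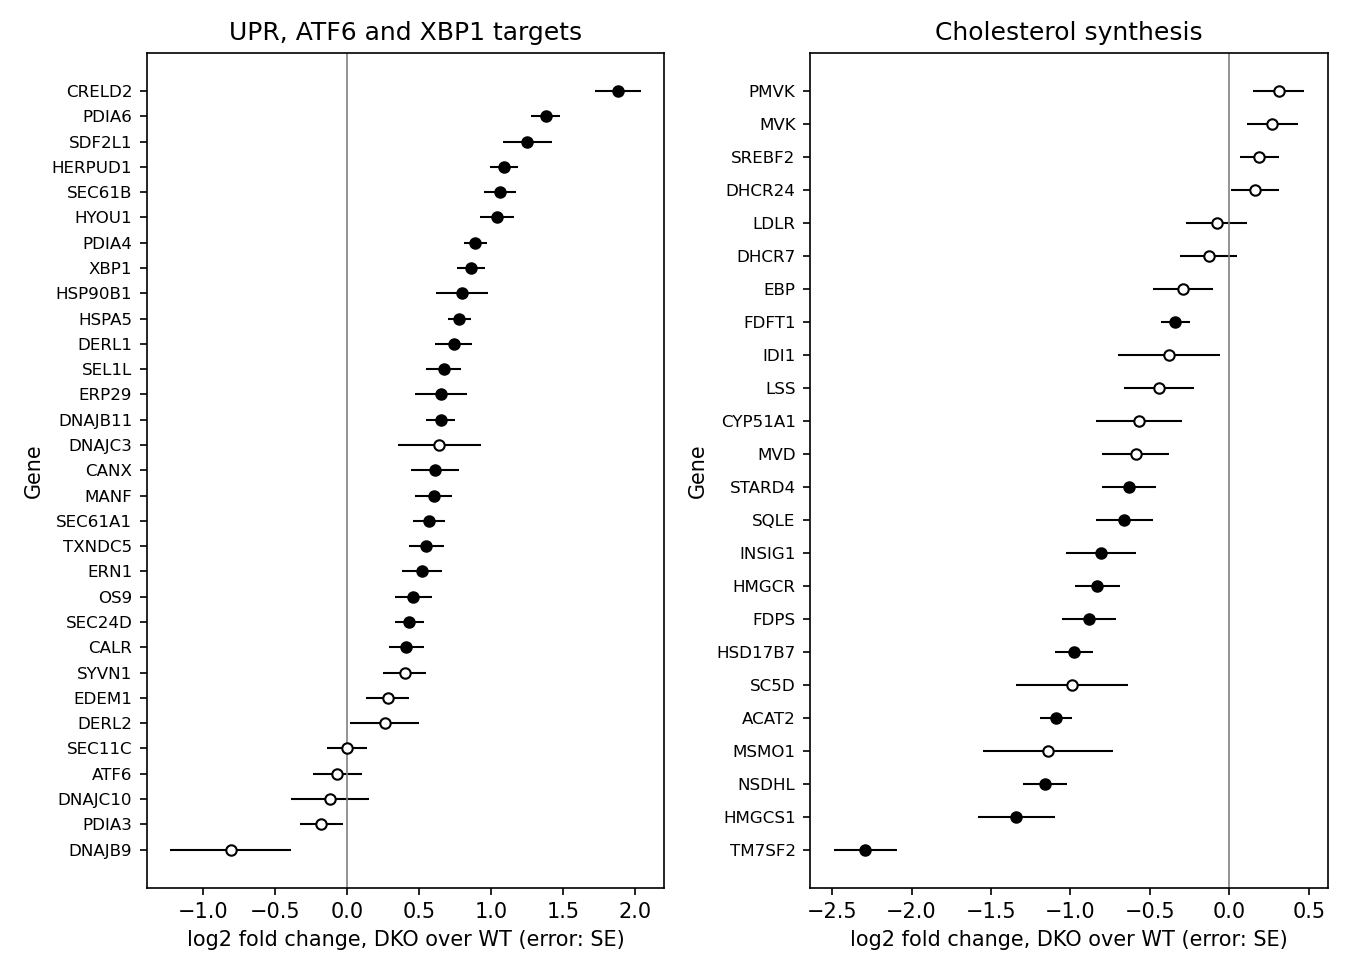
Log2 fold change of DKO over WT (horizontal axis, error bars SE, 3 samples per group) for the tested genes of the ATF6 and XBP1 list and of the cholesterol synthesis list, with filled points for genes called by edgeR. Called genes lie above 0 in the first list (22 of 31) and below 0 in the second (11 of 24).

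In the remaining lists of the ER and secretory pathway, called genes went both ways and camera made no call. Among 24 ER-shaping genes, 7 were higher and 2 lower (7 and 2 adjusted over the list alone, and 10 and 8 of 25 without DKO replicate 3; camera adjusted p = 0.92). REEP2, a tubule-shaping protein gene, rose from 11.4 ± 0.284 to 50.4 ± 8.43 FPKM (2.20, SE 0.17) and the sheet protein gene CKAP4 from 69.2 ± 0.555 to 100 ± 3.44 (0.58, SE 0.09), while RAB3GAP2 (-1.0, SE 0.12) and TMCC1 (-1.0, SE 0.13) fell. Of 46 genes of COPII and the early secretory pathway, 15 were higher and 3 lower (14 and 3 adjusted over the list alone, and 29 and 9 without DKO replicate 3; camera adjusted p = 0.18, and 0.018 without DKO replicate 3). They include ARCN1 (1.23, SE 0.14), ERGIC1 (1.08, SE 0.17), GOSR2 (0.76, SE 0.10) and the KDEL receptor gene KDELR2 (0.65, SE 0.10). Of 42 genes of N-glycosylation and the translocon, 12 were higher and 5 lower (12 and 5 adjusted over the list alone, and 26 and 11 without DKO replicate 3; camera adjusted p = 0.24). SEC61G, a translocon subunit gene, rose from 91.7 ± 6.2 to 1290 ± 510 FPKM (3.85, SE 0.25), ALG12 rose by 1.78 (SE 0.14), TUSC3 by 1.06 (SE 0.11) and SRPRA by 1.02 (SE 0.14). Of 22 ER calcium genes, 6 were higher and 5 lower (6 and 5 adjusted over the list alone, and 10 and 7 without DKO replicate 3; camera adjusted p = 0.92), with RCN3 up from 11 ± 0.949 to 107 ± 8.79 FPKM (3.34, SE 0.16) and the calcium pump gene ATP2A2 up by 0.59 (SE 0.08). Of 16 genes of ER-phagy and UFMylation, 2 were higher and 3 lower (2 and 3 adjusted over the list alone, and 6 and 6 without DKO replicate 3; camera adjusted p = 0.99). The ER-phagy receptor gene RETREG3 fell (-0.64, SE 0.12) and CDK5RAP3 rose (0.81, SE 0.19). Without WT replicate 3, CDK5RAP3 was no longer called (0.73, edgeR adjusted p = 0.054). Of 32 genes of ER contact sites, 3 were higher and 6 lower (2 and 6 adjusted over the list alone, and 12 and 15 without DKO replicate 3; camera adjusted p = 0.92). The sterol transporter gene GRAMD1C was at 0 counts in DKO and at least 5.32-fold lower, and GRAMD1B rose (0.84, SE 0.16). Fewer genes were also called without WT replicate 1, 2 or 3, with 9 higher and 0 to 1 lower for COPII, 6 and 1 to 2 for N-glycosylation, 5 and 2 to 3 for ER calcium, and 0 to 1 and 1 to 2 for ER-phagy. Without DKO replicate 1 or 2, COPII had 1 lower, and without DKO replicate 2 N-glycosylation had 3 lower.

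Lipid and organelle lists also held changes in both directions without a camera call. The share of genes called was slightly above the 45.5% of all tested genes for fatty acid synthesis and lipid droplets. It was below that in the other lists of this paragraph. Of 18 fatty acid synthesis genes, 5 were higher and 4 lower (5 and 5 adjusted over the list alone, and 7 and 10 without DKO replicate 3; camera adjusted p = 0.92). ACLY (-0.89, SE 0.10) and the desaturase gene SCD (-0.81, SE 0.10) fell and ACSL1 (0.63, SE 0.11) rose. Of 23 lipid droplet genes, 7 were higher and 4 lower (7 and 4 adjusted over the list alone, and 8 and 11 without DKO replicate 3; camera adjusted p = 0.92), with the monoglyceride lipase gene MGLL lower (-1.92, SE 0.13) and the phosphatidate phosphatase genes LPIN1 (0.69, SE 0.10) and LPIN2 (0.72, SE 0.10) higher. Of 26 phospholipid synthesis genes, 3 were higher and 5 lower (3 and 5 adjusted over the list alone, and 10 and 9 without DKO replicate 3; camera adjusted p = 0.99), with PCYT1B at 2.61 ± 0.575 FPKM in WT and 0.09 ± 0.0624 in DKO (-4.64, SE 0.38, and -5.26 without DKO replicate 1). Of 40 autophagy genes, 6 were higher and 7 lower (5 and 7 adjusted over the list alone, and 13 and 16 without DKO replicate 3; camera adjusted p = 0.92). MAP1LC3A (-2.49, SE 0.19) and BECN1 (-0.82, SE 0.10) fell, and ATG4D (1.19, SE 0.14) and EPG5 (0.80, SE 0.09) rose. Of 40 lysosomal genes, 10 were higher and 7 lower (9 and 6 adjusted over the list alone, and 15 and 15 without DKO replicate 3; camera adjusted p = 0.92). GPNMB (-2.82, SE 0.14), LAMP2 (-1.32, SE 0.19) and NEU1 (-1.29, SE 0.19) fell, and the proton pump gene ATP6V1B2 (0.50, SE 0.08) rose. Of 34 peroxisome genes, 2 were higher and 12 lower (2 and 12 adjusted over the list alone, and 7 and 16 without DKO replicate 3; camera adjusted p = 0.37), with the catalase gene CAT lower (-1.47, SE 0.11). Of 65 nuclear-encoded genes of oxidative phosphorylation, 9 were higher and 9 lower (4 and 6 adjusted over the list alone, and 13 and 39 without DKO replicate 3; camera adjusted p = 0.99), and of 26 genes of mitochondrial dynamics, 4 were higher and 2 lower (3 and 1 adjusted over the list alone, and 10 and 13 without DKO replicate 3; camera adjusted p = 0.99). The oxidative phosphorylation list lay 0.47 higher (median log2) in DKO replicate 3 than in DKO replicates 1 and 2, and without that sample its camera adjusted p was 0.11. In fits without WT replicate 1, 2 or 3, 2 to 4 fatty acid synthesis genes were higher and 3 to 4 lower, as were 4 and 3 of lipid droplets, 3 and 6 of autophagy and 6 and 4 of the lysosome. In the same fits the counts were 2 and 7 to 9 for peroxisomes, 1 to 2 and 4 to 5 for oxidative phosphorylation, and 2 to 3 and 0 to 1 for mitochondrial dynamics. Without DKO replicate 1 or 2 the lysosome had 4 lower. Without DKO replicate 1 oxidative phosphorylation had 5 lower, and without DKO replicate 2 mitochondrial dynamics had 1 lower. The 13 mitochondrially encoded genes of the list were not analysed here.

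Camera called none of the adhesion, matrix and cell identity lists on log2 CPM. Of 52 genes of collagens and extracellular matrix, 19 were higher and 19 lower (19 and 19 adjusted over the list alone; median 0.05, mean -1.02, camera direction down, adjusted p = 0.92). COL5A2 fell from 41.1 ± 1.82 to 1.42 ± 0.0379 FPKM (-4.81, SE 0.11), and COL11A1 fell from 31.6 ± 0.0781 FPKM to 3 counts in the DKO libraries together, a ratio of 3330 (95% counting interval 1140 to 16200), and without DKO replicate 3 a ratio of 6450 (1160 to 255000). Of 40 integrin and focal adhesion genes, 9 were higher and 16 lower (9 and 16 adjusted over the list alone, and 13 and 26 without DKO replicate 3; camera adjusted p = 0.24). ITGB3 (-4.35, SE 0.16) and ITGB4 (-4.90, SE 0.27) fell and ITGA11 (4.53, SE 0.19) rose. Of 18 epithelial markers, 6 were higher and 10 lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.24): the E-cadherin gene CDH1 fell from 4.84 ± 0.0814 to 0.0867 ± 0.0153 FPKM (-5.69, SE 0.17) and CLDN4 from 48.2 ± 3.13 to 0.823 ± 0.136 (-5.82, SE 0.18), while MUC1 rose (2.47, SE 0.16). On log2 FPKM with pseudocounts of 0.1 and 0.01, the camera adjusted p of the epithelial list was 0.049 and 0.046. Of 15 mesenchymal markers, 6 were higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.92), with the receptor genes PDGFRA (6.10, SE 0.20) and PDGFRB (3.23, SE 0.18) higher and MMP14 at least 204-fold lower. Of 11 smooth muscle markers, 5 were higher and 3 lower (5 and 3 adjusted over the list alone, and 7 and 5 of 12 without DKO replicate 3; camera adjusted p = 0.92). CNN1 (2.44, SE 0.30) rose and MYLK (-2.59, SE 0.14) fell. Of 4 endothelial markers tested, 2 were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.18). Many markers fell under the filter on low counts, so these counts cover only part of each list. Tested were 4 of 12 endothelial, 6 of 14 immune cell and 11 of 17 smooth muscle markers present in the data. For neuronal, mesenchymal and epithelial markers it was 11 of 20, 15 of 20 and 18 of 30. Of 6 immune cell markers, 2 were higher and 1 lower (2 and 1 adjusted over the list alone; median 0.36, mean -0.95, camera adjusted p = 0.99), with CD8A at 0 counts in DKO and at least 24-fold lower and ITGAX higher (1.77, SE 0.22). Of 11 neuronal markers, 3 were higher and 4 lower (5 and 4 adjusted over the list alone, and 5 and 5 without DKO replicate 3; median 0.29, camera direction down, adjusted p = 0.99), and UCHL1 fell from 101 ± 2.48 FPKM to 2 counts in DKO, a ratio of 2790 (95% counting interval 772 to 23000), while RBFOX3 rose (2.73, SE 0.13). Smooth muscle markers higher numbered 3 without WT replicate 1, and immune cell markers higher 1 without WT replicate 3.

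**Figure D4:**
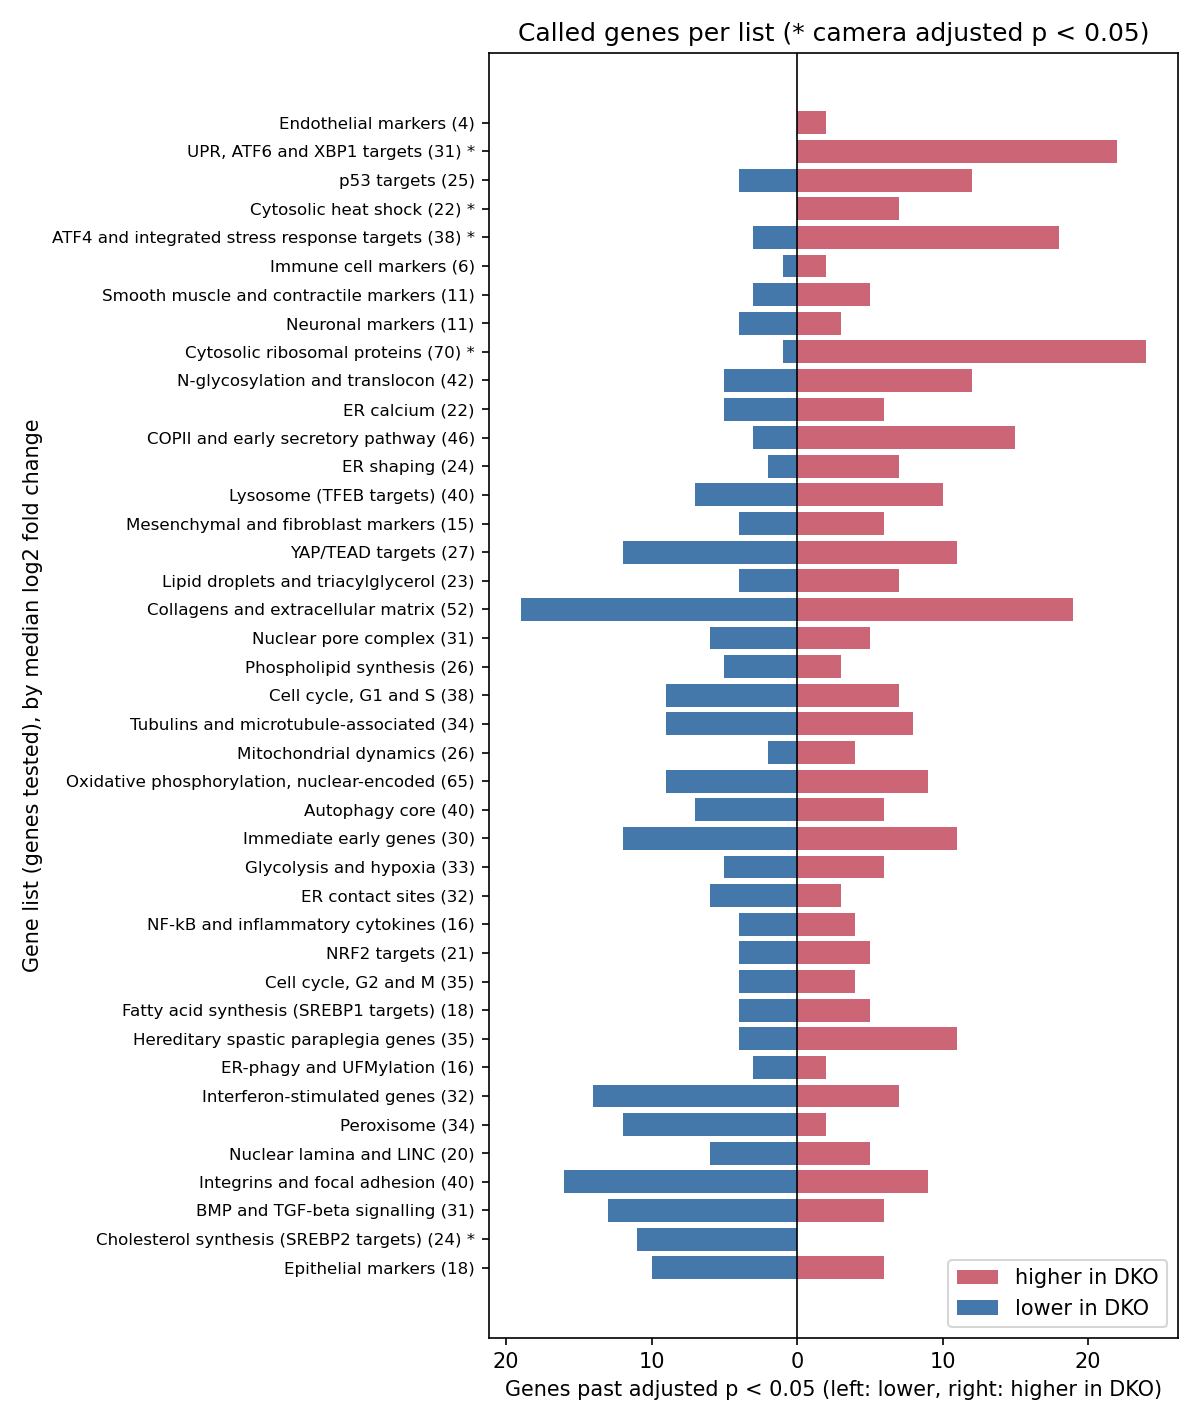
Number of genes past an adjusted p of 0.05 in edgeR (horizontal axis) in each of the 41 gene lists, with genes higher in DKO to the right and lower to the left, and the number tested in brackets. Stars mark the 5 lists past camera, of which cholesterol synthesis has 11 genes lower and 0 higher and the ATF6 and XBP1 list 22 higher and 0 lower.

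The remaining signalling and stress lists were not called by camera. Of 31 BMP and TGF-beta genes, 6 were higher and 13 lower (6 and 14 adjusted over the list alone, and 10 and 20 of 33 without DKO replicate 3; camera adjusted p = 0.41), with the ligand genes BMP7 (3.39, SE 0.15) and BMP6 (3.86, SE 0.28) higher and the receptor gene BMPR2 (-1.73, SE 0.11) and SMAD7 (-1.80, SE 0.12) lower. Of 27 YAP/TEAD targets, 11 were higher and 12 lower (11 and 12 adjusted over the list alone; camera adjusted p = 0.99). ANKRD1 (3.58, SE 0.15) and CCN2 (1.77, SE 0.08) rose and NUAK2 (-1.60, SE 0.11) fell. Of 32 interferon-stimulated genes, 7 were higher and 14 lower (10 and 14 adjusted over the list alone, and 12 and 14 of 33 without DKO replicate 3; camera adjusted p = 0.99). BST2 (2.17, SE 0.25) rose and OAS3 (-2.00, SE 0.23) fell. Of 16 NF-kB and cytokine genes, 4 were higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.99), with the NF-kB inhibitor gene TNFAIP3 lower (-3.09, SE 0.12) and IL11 higher (1.22, SE 0.10). Of 30 immediate early genes, 11 were higher and 12 lower (11 and 12 adjusted over the list alone; camera adjusted p = 0.99). JUNB (-3.32, SE 0.13) fell and NR4A1 (2.54, SE 0.20) rose. Of 25 p53 targets, 12 were higher and 4 lower (12 and 5 adjusted over the list alone; camera adjusted p = 0.26). The cell cycle inhibitor gene CDKN1A rose (1.48, SE 0.10) and PLK2 fell (-1.02, SE 0.09). Of 21 NRF2 targets, 5 were higher and 4 lower (5 and 4 adjusted over the list alone, and 6 and 10 without DKO replicate 3; camera adjusted p = 0.92). The heme oxygenase gene HMOX1 fell (-1.40, SE 0.16) and the glycine transporter gene SLC6A9 rose (1.57, SE 0.16). Of 33 genes of glycolysis and hypoxia, 6 were higher and 5 lower (6 and 5 adjusted over the list alone, and 9 and 14 without DKO replicate 3; median -0.08, camera direction up, adjusted p = 0.99). The glucose transporter gene SLC2A1 (2.01, SE 0.09) and HK2 (1.63, SE 0.10) rose and VEGFA (-0.93, SE 0.09) fell. Again without WT replicate 1, 2 or 3, 7 p53 targets were higher, and 8 to 9 interferon-stimulated genes lower. The BMP and TGF-beta genes lower numbered 8 without WT replicate 3, and the NRF2 targets higher 3 without WT replicate 2.

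Cell cycle, cytoskeletal and nuclear lists likewise held called genes of both directions without a camera call. Of 38 genes of G1 and S phase, 7 were higher and 9 lower (7 and 9 adjusted over the list alone, and 13 and 18 without DKO replicate 3; camera adjusted p = 0.99), with CCNE1, which encodes cyclin E1, lower (-1.69, SE 0.10) and GINS3 higher (0.74, SE 0.10). Of 35 genes of G2 and mitosis, 4 were higher and 4 lower (3 and 2 adjusted over the list alone, and 10 and 15 without DKO replicate 3; camera adjusted p = 0.92). CKS2 (1.03, SE 0.09) rose and CENPF (-1.37, SE 0.19) fell. Of 34 tubulin and microtubule genes, 8 were higher and 9 lower (10 and 10 adjusted over the list alone, and 12 and 16 without DKO replicate 3; median -0.03, camera direction up, adjusted p = 0.99), with the tubulin acetyltransferase gene ATAT1 lower (-1.65, SE 0.18) and the kinesin gene KIF5C higher (1.97, SE 0.23). Of 31 nuclear pore genes, 5 were higher and 6 lower (3 and 6 adjusted over the list alone, and 13 and 10 without DKO replicate 3; median 0.02, camera direction down, adjusted p = 0.99). TPR (-1.05, SE 0.10) fell and NUP98 (0.45, SE 0.09) rose. Of 20 genes of the nuclear lamina and its linkers, 5 were higher and 6 lower (5 and 7 adjusted over the list alone, and 6 and 11 without DKO replicate 3; camera adjusted p = 0.92). SYNE2 (-1.11, SE 0.10) fell and LMNB1 (0.48, SE 0.08) rose. Of 35 genes of hereditary spastic paraplegia, a disease group that includes ATL1, 11 were higher and 4 lower (11 and 4 adjusted over the list alone, and 15 and 15 of 36 without DKO replicate 3; median -0.13, camera direction up, adjusted p = 0.92). KIF1A (1.53, SE 0.15) rose and L1CAM (-2.13, SE 0.17) fell. Likewise without WT replicate 1, 2 or 3, 6 to 7 spastic paraplegia genes were higher and 2 to 4 lower, 3 and 2 of G2 and mitosis, 5 to 6 and 4 to 7 of tubulins, 3 to 4 and 4 to 5 of the lamina, and 1 and 4 of the nuclear pore, which had 3 higher without DKO replicate 1. The median and the mean log2 fold change differed in sign for phospholipid synthesis, lysosome, matrix, YAP/TEAD, mesenchymal, immune, neuronal, mitochondrial dynamics, spastic paraplegia, tubulin and nuclear pore lists.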

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

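ATL2 and ATL3 stayed lower in DKO and past the threshold in each of 17 alternatives, with log2 fold changes from -2.42 to -1.99 and from -2.98 to -2.67. The count of called genes ranged from 4266 without WT replicate 3 to 9880 without DKO replicate 3 when single samples were left out, and fewer samples entered those fits. Without DKO replicate 3 the DKO samples left lie close together. Across genes they differed by an SD of 0.15 on the log2 scale, against 0.67 for its deviation from them. The 2-fold count ranged from 2776 to 3080. At an adjusted p below 0.01, 3902 genes were called. Limma on log2(FPKM + 1) called 1591 genes at the 2-fold limit (2092 and 2135 with pseudocounts of 0.1 and 0.01), 1626 with an FPKM filter of 0.1 and 1049 with a filter of 5, which also left 3859 genes called without the limit. With the same test, unit and filter, the pseudocount alone moved the 2-fold count from 1591 to 2135, so it accounts for a part of the lower counts. The stricter filter tests fewer genes. Test, unit and filter also differ from edgeR, and the cause of the rest was not tested. The same-numbered samples did not pair: their deviations correlated across genes at 0.02, -0.28 and -0.29, and not every sample correlated best with its own number. With the replicate block 4485 genes were called, and 2818 at the 2-fold limit. Without each single sample in turn, 5 lists were called, but not always the same 5. Without DKO replicate 3 the ribosomal list was lost (camera adjusted p = 0.13) and the COPII list gained (0.018). With an estimated correlation camera called 0 lists (3 at an unadjusted p below 0.05): its adjusted p was 0.25 for ATF6 and XBP1 targets, 0.66 for ATF4 targets, 0.41 for cholesterol synthesis, 0.41 for heat shock and 0.99 for ribosomal proteins. The cause was not tested. fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 26 lists, but not the ribosomal proteins (0.17). Among the lists it called, fry gave the opposite direction to camera for phospholipid synthesis (0.0084) and immune cell markers (0.00058), which camera had not called. The directions also differed for the lysosome, mesenchymal, mitochondrial dynamics and tubulin lists, which neither method called. The adjusted p of the ribosomal list ranged from 0.0023 to 0.13 without single samples, the highest without DKO replicate 3, and over all 21 alternatives from 0.0023 to 0.99. It was 0.47 after a length trend was removed with a local curve and 0.83 with a local line, both chosen after seeing the data, and the cause of the loss was not tested further. Over the 21 alternatives the adjusted p ranged from 2.7e-06 to 0.25 for ATF6 and XBP1 targets, from 0.0013 to 0.66 for ATF4 targets, from 0.00029 to 0.41 for cholesterol synthesis and from 0.00028 to 0.41 for heat shock. For 181 further named genes, 3028 of 3040 comparisons kept the direction and the side of the threshold, and 12 kept the direction but lost the call, under the block or without a WT sample. Most of these genes were chosen for a small adjusted p or a large change in the main fit, so this does not measure how stable calls are. Of all 5959 calls, 4197, 4311 and 4188 were kept in the same direction without WT replicate 1, 2 and 3. With the replicate block 4474 were kept. The simulated 1.5-fold changes were mostly missed (2% recovered). Far fewer genes changed in the simulation than were called in the data, which makes the adjusted threshold stricter there. The 2% is thus not the share of such changes found here. Smaller changes were called in the data, such as that of ATP6V1B2 (1.41-fold, edgeR adjusted p = 0.0026).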

Other observations

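Tests chosen only after their results were seen were those of depth for DKO replicate 3, of carried-over RNA and HOX genes for the genes near 0, of DKO replicate 3 and list correlation and the share kept without the length trend for the ER and cholesterol lists, the splits for the gene counts and the length correction of the lists as a setting. The HOX genes, which mark the position of a cell's origin along the body axis, were chosen for a closer look after their values were seen. Of 37 tested, 33 were called. In the HOXA cluster 10 of 11 genes were lower in DKO and 1 higher, and in the HOXB cluster 8 of 9 were lower. In the HOXC cluster 7 of 8 were higher and 0 lower, and in the HOXD cluster 6 of 9 were lower and 1 higher. HOXB6 fell from 23.1 ± 0.23 to 0.58 ± 0.21 FPKM (log2 fold change -5.40, SE 0.22), HOXA5 from 40.5 ± 2.0 to 3.06 ± 0.84 (-3.69, SE 0.20), and HOXB2 from 8.47 ± 0.35 FPKM to 0 counts. HOXC6 rose from 7.16 ± 0.75 to 16.8 ± 1.4 FPKM (1.28, SE 0.13) and HOXC8 from 2.07 ± 0.13 to 7.42 ± 1.3 (1.88, SE 0.16).

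Zinc finger genes were frequent among the genes switched off in DKO. Of 9898 genes that matched the annotation and averaged at least 100 counts in WT, 119 had at most 3 counts in every DKO library. They included 20 of 230 genes named ZNF, ZFP, ZSCAN or ZKSCAN, an odds ratio of 9.20 (95% interval 5.28 to 15.3, two-sided Fisher exact p = 3e-12). Zinc finger genes were not among the gene lists fixed before the data were examined, so the test describes the pattern and is no separate support for it. It also treats genes as independent, although several of the 20 neighbour each other, so the interval is too narrow and the p too small. Among the 230, 24 were called higher and 75 lower, 52 and 112 without DKO replicate 3, and 10 to 14 and 56 to 61 without WT replicate 1, 2 or 3.

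DKO replicate 3 stood apart from DKO replicates 1 and 2, with an SD of 0.67 across genes for its deviation on the log2 scale, against 0.15 for the difference between the other DKO samples. A wild-type sample, or one mixed with wild-type cells, is argued against: 128 genes with at most 3 counts in DKO replicates 1 and 2 had a median of 0% of the WT level in DKO replicate 3 and at most 6 counts. Mixing with other cells that also lack these transcripts would give the same values and was not tested. Depth is argued against too: among 3460 genes averaging at least 1000 counts in DKO, where counting noise is small, the SD was 0.59, against 0.064 between DKO replicates 1 and 2. A trend with transcript length removed 6.2% of the variance of the deviation across 10917 genes, so it was not the whole cause, but a part stays open, as Spearman's rho across genes was -0.28 against -0.17 to 0.19 for single WT samples. A separate culture, clone or day is not given in the labels, and no biological explanation was tested.

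Many genes were near 0 counts in one genotype and well expressed in the other: 121 had at most 3 counts in every DKO library and at least 100 on average in WT, and 8 the reverse. Loss of chromosome segments in DKO could not be told apart from other causes: 21 of 119 placed genes had a switched-off neighbour among WT-expressed genes, fewer than the 50% predicted for segment loss, yet the 12 neighbouring pairs exceeded the 0 to 4 of 10000 random placings. The other 98 had none, and several pairs were zinc finger genes, which lie in clusters. The summed DKO level of the genes, 0.11% of WT, says nothing of carried-over RNA, since the genes were chosen for low counts. A difference between the parental and knockout cell stocks, or between clones, may contribute and cannot be told apart from loss of ATL2 and ATL3 here: HOX genes changed by a median log2 size of 1.88, and a second clone or a rescue would be needed.

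Of the tested ATF6 and XBP1 targets, 22 of 31 were higher and 0 lower in DKO (27 and 1 without DKO replicate 3), and of the cholesterol synthesis genes 11 of 24 were lower and 0 higher (19 and 0 without DKO replicate 3, 7 and 0 without WT replicate 1, 2 or 3). DKO replicate 3 alone is argued against by the medians of the lists. Without it the median log2 fold change was 0.49 for ATF6 and XBP1 targets (0.61 with it). For cholesterol synthesis it was -0.57 (-0.61 with it). The larger camera adjusted p of both lists was then 0.0014 (range over the alternatives 2.7e-06 to 0.41). That p is weak evidence here, since the 2 DKO samples left lie close together and the spread within groups is smaller. Transcript length as the whole cause is argued against, since with a length trend removed the larger adjusted p was 0.014, the median difference in mean log2 CPM, which is not the fitted fold change, grew from 0.59 to 0.79 for the ATF6 and XBP1 list, and that of the cholesterol list went from -0.64 to -0.54, or 84% of its size (95% bootstrap interval over genes 67 to 102). A part of the cholesterol decrease stays open to length, and the ATF6 and XBP1 median moved away from 0 by more than the 0.2 allowed beforehand, so the size of that change depends on the correction. Correlation between the genes of a list stays open as well, with an adjusted p of 0.41 when it was estimated from these samples, and that loss of atlastins raises ATF6 and XBP1 targets is a hypothesis that these data do not separate from a difference between cell stocks.

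The 6 samples make 10 splits, too few for a share under 0.05. The real split gave 5959 genes and 2872 at the 2-fold limit, and was 1 of the 10 to reach these counts. Each other split gave 0 in edgeR, with at most 379 genes at an unadjusted p below 0.05. These splits put WT and DKO samples in the same group, so the genotype difference widens the spread within groups. Their gene counts are therefore no measure of what chance gives. For the lists, the real split gave 5 and each other split 1 to 3, so list calls also arose with the genotypes mixed.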
